A study of Drosophila melanogaster with 6 samples.

How the data were processed

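RNA-seq was carried out on adult heads of Drosophila melanogaster, with 3 libraries from the w1118 stock (control) and 3 from flies with the dnlg3KO88 allele over the dnlg3KO127 allele (knockout). Per the labels' protocols, total RNA was extracted with Trizol from 100 heads per group, messenger RNA was enriched with oligo(dT), and a service provider sequenced the libraries in triplicate on an Illumina HiSeq 2000. The values analysed are FPKM, which the authors deposited as 1 table of 14796 genes with a column per library. The submitters' processing notes name Bowtie, TopHat, Cufflinks, Cuffdiff and R 3.1.1, and the genome build BDGP5, without saying what each tool was used for. Versions of the other tools, the annotation, the strand setting and the treatment of reads with several matches are not given in the sources used here. Reads from overlapping or antisense genes, and from near-identical gene copies, therefore cannot be told apart with certainty. Oligo(dT) enrichment covers small RNA genes poorly, and for very short transcripts FPKM divides few fragments by a short length.

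The table names genes by symbol and FlyBase identifier and holds no coordinates. Of its 14796 identifiers, 13461 matched the BDGP6 annotation of Ensembl release 115, which was used for current symbols, merged exon lengths, chromosome arms and the location of Nlg3. No cell of the table was 0. The value 0.0251 filled 2845 to 3446 genes per library and all libraries for 1801 genes, and 25 cells lay below it. It was read as a fill value for genes with no measured expression, so no fold is given for a gene at this value in all libraries of a genotype. FPKM sums to no fixed total, and the knockout columns summed to more than the control columns, so a few strongly expressed genes or the scaling used by the authors can move all other values of a column.

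Depth was compared through the steps between low values. Between 0.03 and 0.5 FPKM, a gene with the same number of fragments in a pair of libraries shows the ratio of their depths, and the most frequent ratio to control library 1 was taken (tolerance 0.005 on the log2 scale). It was shared by 27.8% to 36.1% of 364 to 547 genes compared and gave the relative depths listed in the results. Absolute read totals were not analysed here, so no counting interval is given, and the precision of each value is described by the spread of the 3 libraries.

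FPKM values were tested as log2(FPKM + 1) in limma 3.58.1 under R 4.3.3, with a moderated test whose prior follows the mean (two-sided), for genes with a mean FPKM of at least 1 over the 6 libraries. P-values were adjusted by the Benjamini-Hochberg method over the 10041 genes kept, with a threshold of 0.05. Log2 fold changes are on the log2(FPKM + 1) scale, which understates the change of low genes, and are given with their standard errors. Tables were read with Python 3.11.15 and pandas 2.3.3, and figures drawn with matplotlib 3.10.9. The labels name no batch, so none was modelled.

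Before the data were examined, 30 gene lists were fixed: 9 immune lists (antimicrobial peptides, Bomanins, peptidoglycan recognition, Toll, Imd, JAK-STAT, lysozymes, melanisation and antiviral factors) and lists for synaptic, sensory, metabolic, stress, clock, sex and tissue genes, with the ribosomal proteins and the mitochondrial genome. Each list with at least 4 tested members was compared with the other genes by camera in limma, with a preset correlation between genes of 0.01 and Benjamini-Hochberg adjustment over 28 lists. The alternatives were camera with an estimated correlation and the rotation test fry. Camera with an estimated correlation also tests on the few residual degrees of freedom of the fit, which raises p-values by itself. Fry asks whether the genes of a list move one way without comparing them with other genes. Some genes stand in more than 1 list, such as Pdf, Nplp2, CG6361, CG8193, brp and n-syb.

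Genes were named by a rule fixed at the same time. It takes Nlg3 and 5 related genes, the 12 largest rises and 12 largest falls among changed genes whose 3 knockout values lie on one side of the 3 control values, and up to 4 changed members of each list with the smallest adjusted p (up to 8 for the first 6 immune lists). It adds w, roX1, roX2, Yp1, Yp2 and Yp3 as checks of the stocks and of the sex of the flies. Clk, cry, the clock and heat shock genes added to their plot, and list members named as exceptions fall outside it.

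The test was checked on simulated values for the same 10041 genes, built from the means and spread of the real libraries. It recovered 46%, 64%, 94% and 98% of 50 genes changed by 0.5, 1, 2 and 4 on the log2 scale, and 13 of 17 genes of a simulated list raised by 1. It called 8 of the 9824 unchanged genes, 4.65% of its 172 calls. Far fewer genes were changed in the simulation than the 4337 called in the real data. The Benjamini-Hochberg cutoff depends on that share, so these rates do not carry over to the real comparison.

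Alternatives fixed beforehand were pseudocounts of 0.1 and 0.5, no filter or a mean FPKM of at least 5, median-of-ratios scaling, quantile normalization, columns rescaled to a sum of 1000000, a prior without trend, a robust prior, the replicate number as a block, each library left out in turn, an adjusted p below 0.01 and an absolute log2 fold change of at least 1. Added after seeing the data were the removal of a smooth trend of log2 values on merged exon length in each library (loess, span 0.3) and a test without small RNA genes. The removal of the length trend kept only genes with a merged exon length, so some lists lost members in it. GC content was not tested here.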

Results

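The series held 6 RNA-seq libraries from adult heads of Drosophila melanogaster, 3 from the w1118 control stock and 3 from flies carrying the dnlg3KO88 allele over the dnlg3KO127 allele. The gene affected by both alleles, Nlg3 (also written DNlg3), encodes a neuroligin, a postsynaptic adhesion protein that binds neurexins. The title of the series names a C-terminal fragment of this protein that enters the nucleus and the regulation of innate immune response genes, so the comparison of the genotypes asks which genes, immune genes among them, differ in the knockout. The table analysed gave FPKM (fragments per kilobase of transcript and 1000000 mapped fragments) for 14796 genes in each library. Summed FPKM was 566927, 569629 and 584024 in the control libraries and 695719, 698568 and 714762 in the knockout libraries, and 9798 to 9923 genes reached an FPKM of 1. The read totals behind these values were not analysed here. The steps between low FPKM values put the depth of control libraries 2 and 3 at 1.08 and 0.973 times that of control library 1. Knockout libraries 1, 2 and 3 came to 0.547, 1 and 0.823 times that depth on the same measure, so low values were least precise in knockout library 1. Across genes, log2(FPKM + 1) correlated at 0.976 or more between libraries of the same genotype and at 0.953 or less between genotypes. The labels give 100 heads per group and do not say whether the libraries of a genotype came from separate collections, so p-values measure only the spread between these samples, which may be technical.

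Nlg3 itself, listed as CG34127 (FBgn0083963), was lower in each knockout library than in each control library. Its FPKM was 14.3, 15 and 16 in control libraries 1 to 3 and 8.62, 8.51 and 7.21 in knockout libraries 1 to 3. The mean was 15.1 ± 0.81 in the control and 8.11 ± 0.78 in the knockout (SD, n = 3), a ratio of 0.537. The log2 fold change of FPKM + 1 was −0.82 ± 0.10 (SE), with a limma adjusted p of 0.000645. In the BDGP6 annotation of Ensembl release 115, Nlg3 lies on the minus strand of chromosome 3R from 7570281 to 7639434, with 6650 bp of merged exons. The labels do not say which part of the gene the alleles remove, and a gene-level FPKM pools the exons, so the remaining signal cannot be placed along the gene.

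The fixed list of neuroligins and neurexins had 6 tested members, of which 0 were higher, 2 were lower (Nlg3 and Nrx-1) and 4 did not pass. Nrx-1, a presynaptic neurexin, changed by −0.33 ± 0.07 (adjusted p = 0.00724), and by −0.059, not past the threshold, once the exon length trend described with the length plot was removed. Nlg1 (CG31146) had a log2 fold change of 0.24 ± 0.15 (adjusted p = 0.236) and Nlg2 (neuroligin) of −0.10 ± 0.07 (adjusted p = 0.281). Nlg4 (CG34139) had −0.21 ± 0.09 (adjusted p = 0.0896) and Nrx-IV, a septate junction neurexin, 0.15 ± 0.07 (adjusted p = 0.125). Nlg2 and Nlg4 were called lower, at −0.20 and −0.32, under quantile normalization of the columns. The median of the list was −0.15 (camera adjusted p = 0.194), and −0.26 under quantile normalization, −0.44 after rescaling to 1000000 and 0.0061 after removal of the length trend.

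Of 10041 genes with a mean FPKM of at least 1, 4337 (43.2%) differed between the genotypes at an adjusted p below 0.05, with 2531 higher and 1806 lower in the knockout. In 2523 of the higher genes and 1800 of the lower genes the 3 knockout values did not overlap the 3 control values. Such separation held for 55.5% of the tested genes, against 10% by chance for 3 libraries against 3. The change was at least 1 on the log2 scale for 775 higher and 304 lower genes, and below 0.5 for 1745 of the changed genes. The split into higher and lower genes rested on the scale of the columns. As deposited, 58.4% of the calls were higher. Quantile normalization gave 1890 higher and 2732 lower genes (40.9% higher), and rescaling each column to a sum of 1000000 gave 1444 higher and 3924 lower (26.9% higher). The median log2 fold change of the tested genes was 0.038 as deposited, −0.079 after quantile normalization and −0.24 after rescaling to 1000000, and the list tests below compare each list with the other genes, relative to that shift.

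Of 30 gene lists fixed beforehand, 28 had at least 4 tested members, and 21 of them passed the camera test at its preset correlation, 16 higher and 5 lower in the knockout. With an estimated correlation between genes 10 of the lists passed, namely antimicrobial peptides, Bomanins, peptidoglycan recognition proteins, neuropeptides, phototransduction, cytochrome P450 and glutathione S-transferases, heat shock proteins, fat body, gut enzymes and ribosomal proteins. That alternative also uses fewer degrees of freedom, so a lost call need not reflect correlation between genes. The JAK-STAT and antimicrobial peptide lists had estimated correlations of −0.0067 and −0.031, below the preset 0.01. Their camera adjusted p still rose, from 0.00116 to 0.0568 and from 6.42e-12 to 0.0164. The rotation test fry, which tests a list against no change and not against other genes, passed 27. Counts of members adjusted over the list alone equalled those over all genes tested for 19 lists and are given beside them for the other 9. Members named below outside the naming rule were chosen after their values were seen.

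**Figure D1:**
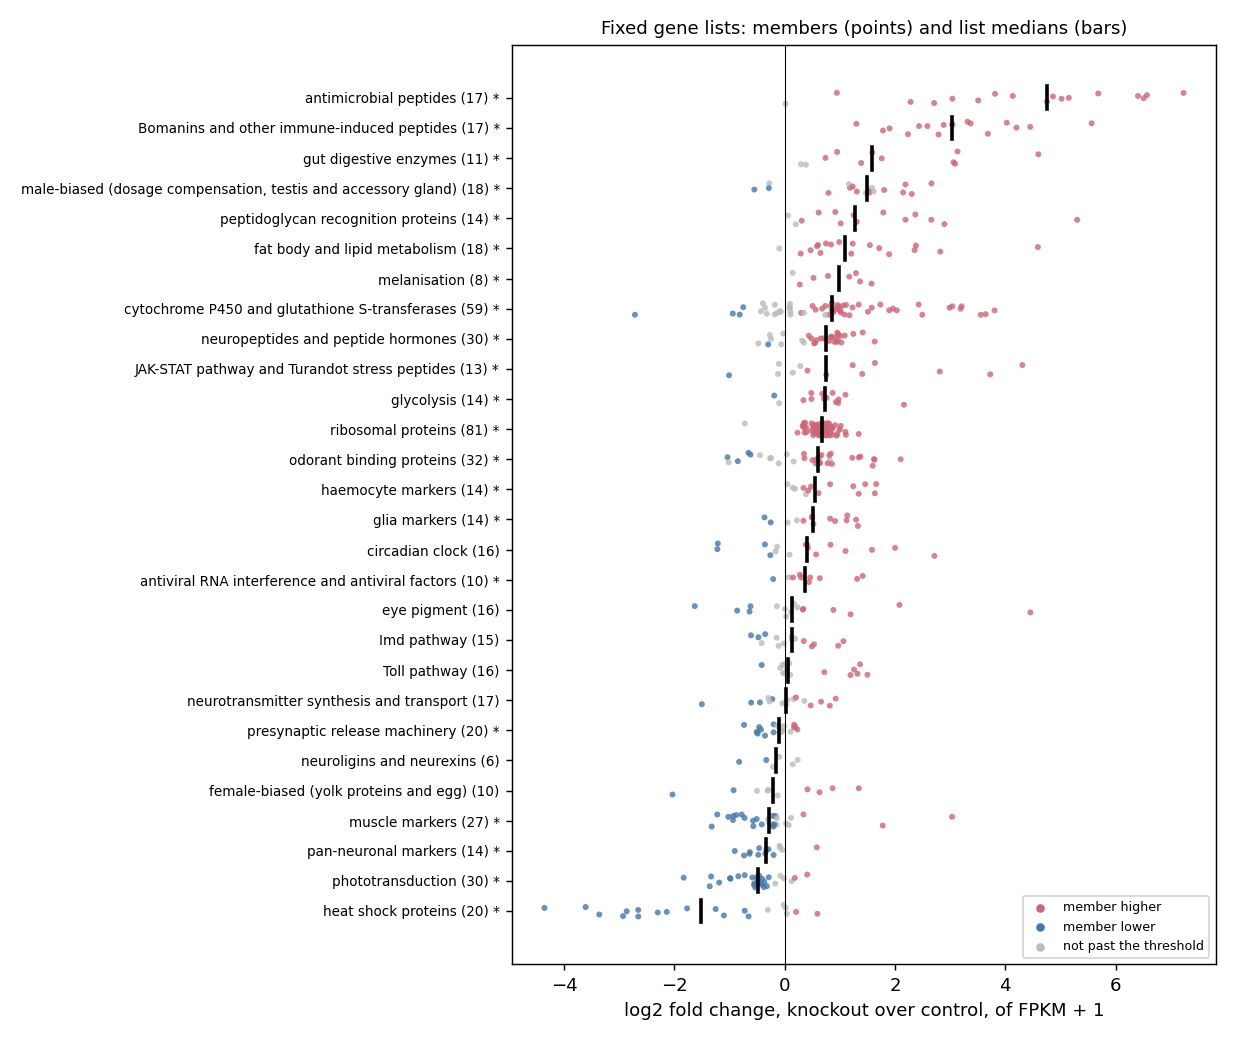
Log2 fold change (knockout over control, of FPKM + 1, x axis) of the tested members of 28 gene lists (rows, with the number tested), where each point is a gene, the black bar is the median of the list and an asterisk marks a camera adjusted p below 0.05. The medians run from 4.76 for antimicrobial peptides to −1.51 for heat shock proteins, and those of the Toll, Imd, neurotransmitter and eye pigment lists change sign under another scaling.

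Of the 28 lists, those of secreted immune peptides had the highest medians at the main filter, a mean FPKM of at least 1. Of 17 tested antimicrobial peptide genes, 16 were higher in the knockout and 0 lower, also when adjusted over the list alone, with a median log2 fold change of 4.76 (camera adjusted p = 6.42e-12). The member that did not pass was dro4, at 0.019. Diptericin A (listed as Dpt), an Imd-dependent peptide, rose from 10.4 ± 3.06 to 1680 ± 186 FPKM (SD, n = 3), a 161-fold difference and a log2 fold change of 7.23 ± 0.20 (limma adjusted p = 7.46e-07). Drosocin (Dro) rose from 44.3 ± 12 to 4190 ± 258 FPKM and Metchnikowin (Mtk) from 27.8 ± 4.71 to 2593 ± 49.1 FPKM. Drosomycin (Drs), an antifungal peptide controlled largely by the Toll pathway, rose from 36.5 ± 8.39 to 1077 ± 70.6 FPKM, a log2 fold change of 4.87 ± 0.15. AttC, DptB, AttA and CecC changed by 6.41, 5.69, 5.15 and 4.76. AttA and AttB, and the cecropin genes among themselves, are near-identical copies whose reads the processing could have split, so their separate values are uncertain. The gene list of the fat body, a tissue that secretes these peptides, was higher as well, with a median of 1.10.

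Bomanins, short Toll-dependent peptides, and other immune-induced peptides were higher in the knockout for 17 of 17 tested genes, also when adjusted over the list alone, with a median of 3.04 (camera adjusted p = 1.03e-13). IM1 rose from 40.3 ± 1.62 to 673 ± 50.9 FPKM (SD, n = 3) and IM4 from 269 ± 37.5 to 4965 ± 604 FPKM. IM14 rose from 1081 ± 61.1 to 8913 ± 1092 FPKM and had the highest FPKM of any gene in knockout library 3, 10162, where ninaE, the main rhodopsin of the eye, led in the other 5 libraries. The gene edin (CG32185), which acts in the response to bacteria, rose from 0.931 ± 0.35 to 89.9 ± 10.8 FPKM. The 39 genes of the antimicrobial peptide and Bomanin lists together took 1.13 ± 0.018% of the summed FPKM in the control and 7.51 ± 0.13% in the knockout (SD, n = 3).

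**Figure D2:**
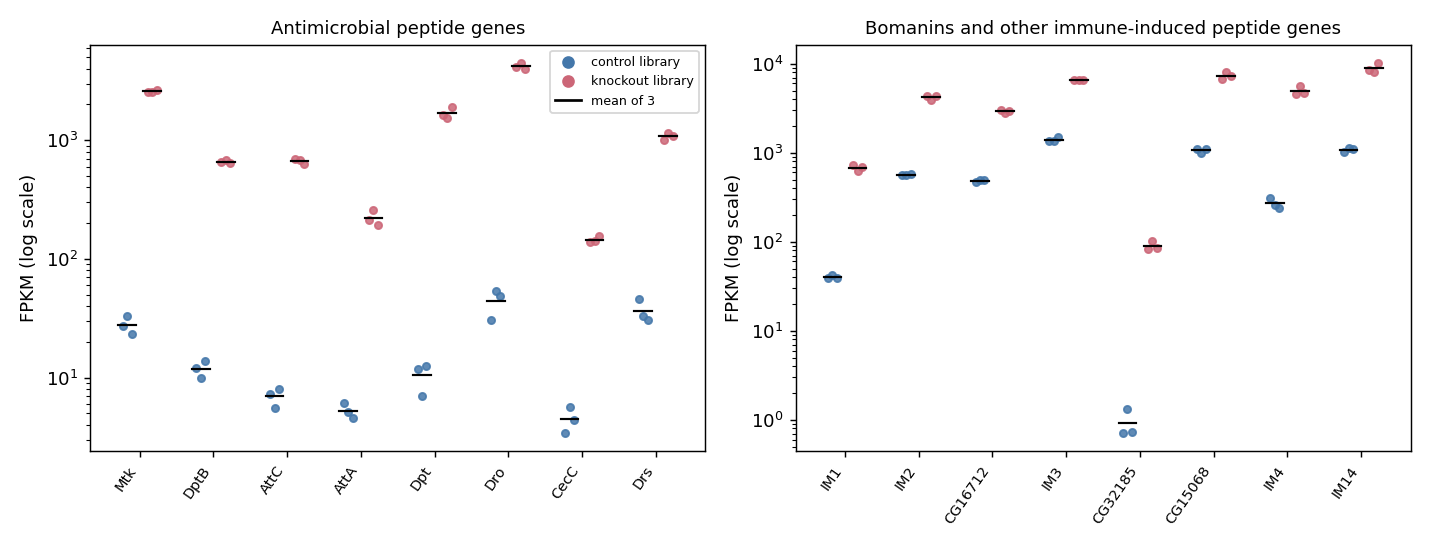
FPKM (log scale, y axis) of 8 antimicrobial peptide genes (left) and 8 Bomanin or other immune-induced peptide genes (right) in each of 3 control (blue) and 3 knockout (red) libraries, with a black line at the mean of 3. For each gene the 3 knockout values lie above the 3 control values, as for Mtk with means of 27.8 and 2593 FPKM.

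Of 14 genes in the peptidoglycan recognition list, 12 were higher, 0 lower and 2 (PGRP-LE and PGRP-LA) not past, with a median of 1.28 (camera adjusted p = 1.17e-06). The list holds receptor and amidase genes of these pathways and also GNBP genes, a separate family. Of the latter, CG13422 (GNBP-like3) and GNBP3 were higher, at 2.90 and 0.92. PGRP-SB1 rose from 13.4 ± 2.25 to 563 ± 28.0 FPKM, and the Imd receptor PGRP-LC from 28.6 ± 0.778 to 58.9 ± 3.62 FPKM (SD, n = 3). PGRP-LB, an amidase that lowers Imd signalling, changed by 2.37 ± 0.10. In the Toll list, 6 of 16 genes were higher, 1 lower and 9 not past, with a median of 0.064 (camera adjusted p = 0.0796). That median turned to −0.088 under quantile normalization and to −0.23 after rescaling to 1000000, where 6 were higher and 9 lower. As deposited, the 6 higher genes were the protease gene SPE, whose product cleaves the Toll ligand, at 1.5 ± 0.12, the serpin gene nec at 1.2 ± 0.05 and CG6361 (Hayan), psh, spirit and grass at 1.37, 1.26, 1.32 and 0.72. The lower gene was Pli at −0.42. The protease gene modSP, the ligand gene spz and the receptor gene Tl had −0.026, 0.0073 and −0.0030 and did not pass. The Toll list passed once the length trend was removed (adjusted p = 0.0304, the lowest of its 20 camera alternatives, which ran up to 0.337).

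In the Imd list, 5 of 15 genes were higher, 3 lower and 7 not past (camera adjusted p = 0.713). The NF-kappaB factor Rel changed by 0.97 ± 0.06 and the pathway inhibitor pirk by 1.07 ± 0.08, while Uev1A changed by −0.61 ± 0.07. The median was 0.13, and −0.011 under quantile normalization, −0.16 after rescaling to 1000000, where 2 were higher and 5 lower, and −0.10 after removal of the length trend. The calls of Pli, ird5 and Tab2 in the Toll and Imd lists were lost without 2, 4 and 5 of the libraries respectively, each left out alone, at an adjusted p of up to 0.0576, 0.0741 and 0.139. In the JAK-STAT list, which holds the secreted Turandot stress peptides, 8 of 13 genes were higher, 1 lower and 4 not past, or 9 higher and 1 lower adjusted over the list alone. Its median was 0.76 (camera adjusted p = 0.00116, and adjusted p = 0.0568 with an estimated correlation). The median was 0.29 without a filter, 0.41 with a minimum mean FPKM of 5, 0.45 under quantile normalization and 0.46 after rescaling to 1000000. TotM, TotC and TotA changed by 4.31 ± 0.09, 3.73 ± 0.08 and 2.81 ± 0.08, and TotX by −1.01 ± 0.17. The receptor dome, the kinase hop and Stat92E had −0.11, −0.12 and 0.15 and did not pass.

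In the melanisation list, 7 of 8 genes were higher, with CG8193 (PPO2) not past and a median of 0.98 (camera adjusted p = 0.00147, and adjusted p = 0.123 with an estimated correlation). Its members included yellow-f2 at 1.58 ± 0.15, CG6361 (Hayan, also in the Toll list) at 1.37 ± 0.15 and the serpin gene Spn27A at 1.29 ± 0.06. In the antiviral list, 8 of 10 genes were higher, 1 (loqs) lower and 1 (r2d2) not past, with a median of 0.37 (camera adjusted p = 0.0191, and adjusted p = 0.149 with an estimated correlation). Its call also ended with a minimum mean FPKM of 5 and after rescaling to 1000000, where 4 were higher and 2 lower with a median of 0.10, and AGO2 had −0.015 against 0.28 as deposited. Under quantile normalization 5 were higher and 1 lower, with a median of 0.22. Vago, a secreted antiviral factor, changed by 1.31 ± 0.13 and ref(2)P by 0.46 ± 0.05. Lysozymes, with 3 tested genes, were too few for the list test, and LysD was listed at the fill value of 0.0251 in the 3 control libraries and at 2.46 ± 1.52 FPKM in the knockout (SD, n = 3). Over the first 6 of these immune lists, from antimicrobial peptides to JAK-STAT, 64 of 92 tested genes were higher and 5 lower, or 59 higher and 19 lower after rescaling to 1000000.

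Outside the immune lists, the largest rises named by the rule included CG10332 at 6.67 ± 0.26 and CG4757 at 5.59 ± 0.07. PebII and Acp54A1, which encode male ejaculatory bulb and accessory gland products, were listed at the fill value of 0.0251 in the 3 control libraries and at 44.2 ± 7.31 and 55.6 ± 22.5 FPKM in the knockout (SD, n = 3). The largest falls outside small RNA genes included CG17298 at −5.32 ± 0.29, CG34217 at −4.98 ± 0.39, CG13043 at −4.69 ± 0.18, CG34301 at −4.45 ± 0.31 and Hsp70Ba at −4.35 ± 0.13. CG8483, CG40298, the cilium gene Tektin-C and Hsp26 followed, at −3.82, −3.79, −3.65 and −3.61. SNCF was listed at the fill value in the 3 knockout libraries and at 14.2 ± 3.53 FPKM in the control. The rule also took 3 snoRNA genes, short RNAs poorly covered by oligo(dT) selection, whose values varied widely within a genotype. In the knockout snoRNA:Me28S-G2703b stood at 662 ± 879 FPKM and in the control at the fill value. In the control snoRNA:Or-CD12 stood at 469 ± 513 FPKM and in the knockout at the fill value. The call of snoRNA:Me28S-G2703a (−6.60 ± 1.80) was lost without each of 5 of the libraries, at an adjusted p of up to 0.0809. Of 129 small RNA genes tested, 4 were higher and 3 lower.

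In the fat body and lipid list, 17 of 18 genes were higher, 0 lower and 1 (Rfabg, the lipophorin precursor) not past, with a median of 1.10 (camera adjusted p = 5.62e-09). The fatty acid desaturase desat1 rose from 560 ± 27.3 to 2870 ± 42.5 FPKM, the storage protein gene Lsp2 from 11.4 ± 0.606 to 87.1 ± 7.27 and the lipase gene CG5932 (magro) from 0.144 ± 0.206 to 26.4 ± 2.98 FPKM (SD, n = 3). Among 59 cytochrome P450 and glutathione S-transferase genes, 39 were higher, 4 (Cyp6a17, GstD10, Cyp4ac1 and Cyp313a1) lower and 16 not past, or 40 higher and 5 lower adjusted over the list alone. Their median was 0.86 (camera adjusted p = 6.78e-08), with Cyp4e3 at 3.21 ± 0.06, Cyp28d1 at 3.04 ± 0.08 and Cyp6w1 at 2.99 ± 0.06. A further 30 tested genes with symbols in Cyp, outside the fixed lists, grouped after seeing the data and including the cyclophilin gene Cyp1, held 11 higher and 5 lower genes with a median of 0.32 (camera adjusted p = 0.578 over 37 symbol families). In glycolysis, 12 of 14 genes were higher, 1 (Hex-A) lower and 1 (Gpdh) not past, with a median of 0.74 (camera adjusted p = 3.79e-05, and adjusted p = 0.149 with an estimated correlation). The median of glycolysis was 0.49 under quantile normalization and 0.44 after rescaling to 1000000. The hexokinase gene Hex-C changed by 2.16 ± 0.14 and Tpi by 0.98 ± 0.06.

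Markers of tissues other than brain and eye also moved. Of 37 gut digestive enzyme genes 11 reached the filter, of which 9 were higher, 0 lower and 2 (Jon74E and LvpH) not past, with a median of 1.59 (camera adjusted p = 6.65e-05). The median was 0.37 without a filter, 3.06 with a minimum mean FPKM of 5 and 2.95 with a pseudocount of 0.1. Several were low in the control, where the amylase gene Amy-p stood at 0.454 ± 0.507 FPKM against 33.1 ± 2.58 in the knockout and alphaTry at 0.487 ± 0.4 against 11.7 ± 1.08 (SD, n = 3). The pair Amy-p and Amy-d, and alphaTry with betaTry, are near-identical copies with uncertain separate values. Of 14 haemocyte (blood cell) markers, 10 were higher, 0 lower and 4 not past, or 11 higher adjusted over the list alone. Their median was 0.55 (camera adjusted p = 0.000123, and adjusted p = 0.073 with an estimated correlation), with the scavenger receptor gene Sr-CI at 1.64 ± 0.10, srp at 1.46 ± 0.07 and Hml at 0.83 ± 0.09, and the median was 0.28 after rescaling to 1000000. Of 27 muscle genes 17 were lower, 3 (TpnC4, fln and TpnC25D) higher and 7 not past, with a median of −0.28 (camera adjusted p = 1.55e-05, and adjusted p = 0.123 with an estimated correlation). Act79B changed by −1.22 ± 0.07, bt by −0.93 ± 0.05 and Mhc, the muscle myosin heavy chain, by −0.88 ± 0.04. The median of the muscle list was −0.64 under quantile normalization, −0.57 after rescaling to 1000000, −0.44 after removal of the length trend and −0.18 without knockout library 2.

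Sex-biased markers went in both directions. In the male-biased list, 11 of 18 genes were higher, 2 (roX1 and msl-2) lower and 5 not past, or 13 higher and 2 lower adjusted over the list alone. The median was 1.5 (camera adjusted p = 0.0195, and adjusted p = 0.149 with an estimated correlation), and with a minimum mean FPKM of 5 the direction of the test reversed at a median of 0.48. With a pseudocount of 0.1 the median was 2.52. The higher members were testis and accessory gland genes at low FPKM, such as ocn from 0.98 ± 0.465 to 8.7 ± 1.47 and Mst84Dc from 0.358 ± 0.576 to 7.36 ± 2.22 FPKM (SD, n = 3). The dosage compensation RNAs roX1 and roX2, made in males, had log2 fold changes of −0.55 ± 0.05 (adjusted p = 0.000265) and −0.28 ± 0.21 (adjusted p = 0.325). In the female-biased list, 4 of 10 genes were higher, 2 (Vm34Ca and Vm26Aa, egg membrane genes) lower and 4 not past (camera adjusted p = 0.689, upward, with a median of −0.21 and a mean of −0.092). With a minimum mean FPKM of 5 the list passed upward with a median of 0.75 (adjusted p = 0.00479, with 0.00479 to 0.955 over its 20 camera alternatives). The yolk protein genes Yp1, Yp2 and Yp3 changed by 0.63 ± 0.07, 0.41 ± 0.06 and 1.34 ± 0.08, and under quantile normalization Yp1 and Yp2 turned to −0.072 and −0.10. The labels do not give the sex of the flies. Since female-biased yolk genes and male-biased testis genes both rose, these checks do not settle whether the mix of sexes differed.

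Pan-neuronal markers tended lower before the length trend was removed, and glial and neuropeptide genes tended higher. The direction of the presynaptic list rested on the processing. Of 14 pan-neuronal markers 10 were lower, 1 (nrv3, at −0.18 under quantile normalization) higher and 3 not past, with a median of −0.34 (camera adjusted p = 8.61e-05, and adjusted p = 0.283 with an estimated correlation). The RNA-binding protein gene elav fell from 102 ± 2.64 to 54 ± 5.62 FPKM and Sh, a potassium channel gene, from 188 ± 4.38 to 121 ± 8.76 FPKM (SD, n = 3). Of 20 presynaptic release genes, 8 were lower, 4 (Rop, shi, Rab3 and comt) higher and 8 not past, with a median of −0.094 (camera adjusted p = 0.0191, and adjusted p = 0.32 with an estimated correlation). Under quantile normalization 14 were lower and 0 higher, with a median of −0.28, and after rescaling to 1000000 15 were lower and 0 higher, with a median of −0.38. The genes shi and comt were below 0 under both scalings, and Rop and Rab3 under the second. The vesicle SNARE gene n-syb changed by −0.73 ± 0.07 and the active zone gene brp by −0.46 ± 0.05. The fixed list also holds dlg1, a synaptic scaffold gene and not itself release machinery, at −0.49 ± 0.05. The pan-neuronal median was −0.61 under quantile normalization and −0.63 after rescaling to 1000000. Removal of the length trend, which kept 11 of the 14 pan-neuronal markers and 18 of the 20 presynaptic genes, ended the calls of both lists. Of the pan-neuronal markers kept, 3 were lower and 2 higher, with a median of −0.10 (camera adjusted p = 0.57, with 1.12e-06 to 0.57 over its 20 camera alternatives). The presynaptic median turned to 0.037 (camera adjusted p = 0.791, with 8.4e-05 to 0.791). Part of these shifts can come from the members lost. Of 17 genes of neurotransmitter synthesis and transport, 5 were higher, 4 lower and 8 not past, or 6 higher and 4 lower adjusted over the list alone (camera adjusted p = 0.713). Their median was 0.030 as deposited and −0.0096, −0.14 and −0.26 under median-of-ratios scaling, quantile normalization and rescaling to 1000000, the last with 2 higher and 9 lower. The decarboxylase gene Ddc changed by 0.93 ± 0.05, and the tyrosine hydroxylase gene ple and ebony (e) by −0.61 ± 0.06 and −1.5 ± 0.11.

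Among 30 neuropeptide and peptide hormone genes, 22 were higher, 1 (Dh) lower and 7 not past, with a median of 0.76 (camera adjusted p = 1.86e-05). Nplp2, also in the haemocyte list, rose from 2362 ± 138 to 5599 ± 263 FPKM (SD, n = 3), while Fmrf changed by 1.63 ± 0.13, Tk by 1.09 ± 0.06 and Ast-C by 0.71 ± 0.04. The median of this list was 0.47 after rescaling to 1000000, with 19 higher and 5 lower, and 0.43 after removal of the length trend, with 17 higher and 3 lower. Of 14 glial markers, 10 were higher, 2 (CG1090 and Eaat2) lower and 2 not past, or 11 higher and 2 lower adjusted over the list alone. Their median was 0.51 (camera adjusted p = 0.00155, and adjusted p = 0.13 with an estimated correlation), with the GABA transporter gene CG1732 (Gat) at 1.33 ± 0.07 and the astrocyte gene CG11910 (alrm) at 1.30 ± 0.08, and it was 0.23 after rescaling to 1000000. Of 32 odorant binding protein genes, 20 were higher, 4 lower and 8 not past, with a median of 0.60 (camera adjusted p = 0.00304, and adjusted p = 0.123 with an estimated correlation). Obp44a changed by 1.62 ± 0.05, Obp56h by 1.60 ± 0.06 and Obp99c by 1.23 ± 0.07. After rescaling to 1000000, 13 were higher and 5 lower, with a median of 0.34. The call of this list ended once the length trend was removed, where 11 were higher and 7 lower with a median of 0.11 (adjusted p = 0.329, with 0.000198 to 0.329 over its 20 camera alternatives).

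Phototransduction genes were lower in the knockout for 24 of 30 members, or 25 adjusted over the list alone, with 2 (Rh2 and Arr1) higher and 4 not past, and Arr1 turned to −0.34 under quantile normalization and −0.11 after rescaling to 1000000. Their median was −0.48 (camera adjusted p = 1.24e-10), and −0.78 and −0.77 under those scalings. The ion channel gene trp fell from 1037 ± 17 to 525 ± 12.1 FPKM, the phospholipase C gene norpA from 492 ± 13.5 to 192 ± 14.8 and the kinase gene rdgA from 308 ± 7.17 to 122 ± 7.02 FPKM (SD, n = 3). In the eye pigment list, 6 of 16 genes were higher, 4 lower and 6 not past, with a median of 0.14 (camera adjusted p = 0.595). That median turned to −0.10 after rescaling to 1000000, with 4 higher and 7 lower. The white gene (w), which encodes a pigment transporter subunit and is mutant in the w1118 stock, stood at 0.766 ± 0.116 FPKM in the control and 37.8 ± 3.11 in the knockout (SD, n = 3). Its log2 fold change was 4.46 ± 0.11 (limma adjusted p = 5.41e-07), and the genotypes thus differed in w expression as well as in Nlg3. The labels do not say whether the w signal comes with the Nlg3 alleles or from elsewhere. Hn changed by 2.08 ± 0.09, while the pteridine genes Pu and se changed by −0.86 ± 0.05 and −1.63 ± 0.12.

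Heat shock genes had the lowest median of the 28 lists. Of 20 tested, 14 were lower, 2 (l(2)efl and Hsp60, the second at −0.083 after rescaling to 1000000) higher and 4 not past, or 15 lower and 2 higher adjusted over the list alone, with a median of −1.51 (camera adjusted p = 7.42e-09). The small heat shock protein genes Hsp26 and Hsp23 fell from 684 ± 47.2 to 55.1 ± 2.49 and from 342 ± 16.6 to 32.5 ± 3.03 FPKM, and the co-chaperone gene stv from 297 ± 4.74 to 86.6 ± 1.29 FPKM (SD, n = 3). Hsp70Bb changed by −2.93 ± 0.08, and the Hsp70 genes are near-identical copies with uncertain separate values. In the circadian clock list, 9 of 16 genes were higher, 4 (Clk, to, CkIIbeta and sgg) lower and 3 not past, or 9 higher and 5 lower adjusted over the list alone, with a median of 0.40 (camera adjusted p = 0.208). After rescaling to 1000000 the counts turned to 5 higher and 7 lower, with a median of 0.12, and under quantile normalization the median was 0.23. The transcripts of tim, vri, per and cwo, which are driven by the CLK and CYC proteins, changed by 2.72 ± 0.06, 2.0 ± 0.08, 1.58 ± 0.10 and 1.10 ± 0.06. Clk, which cycles in antiphase to them, changed by −1.22 ± 0.09, and cry had −0.16 ± 0.06 (adjusted p = 0.0726). Removal of the length trend brought this list past the threshold (adjusted p = 0.0378, the lowest of its 20 camera alternatives, which ran up to 0.464).

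**Figure D3:**
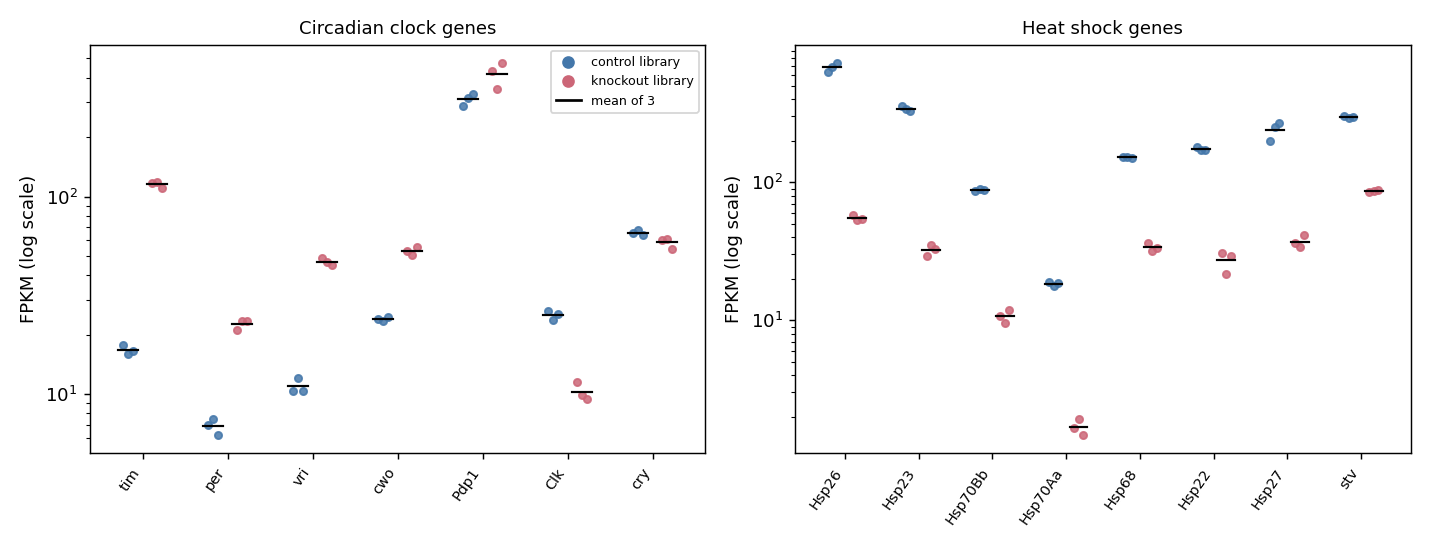
FPKM (log scale, y axis) of 7 circadian clock genes (left) and 8 heat shock genes (right) in each of 3 control (blue) and 3 knockout (red) libraries, with a black line at the mean of 3. The mean of tim is 16.7 FPKM in the control and 115 in the knockout, that of Clk is higher in the control, and the 8 heat shock genes are lower in the knockout, as for Hsp26 with means of 684 and 55.1 FPKM.

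Ribosomal protein genes were higher in the knockout for 79 of 81 members, with 0 lower, 2 (RpS28a and RpS5b) not past and a median of 0.68 (camera adjusted p = 1.58e-23). RpLP1 rose from 1330 ± 13.4 to 2515 ± 8.42 FPKM (SD, n = 3). The median was 0.26 under quantile normalization, with 49 members higher and 5 lower, 0.39 after rescaling to 1000000, and 0.33 after removal of the length trend, with 50 of 70 members higher and 1 lower. No gene of the mitochondrial genome list reached the filter, with 0 of its 37 genes tested.

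Fold changes fell with transcript length across genes, which are not independent replicates. Spearman's rho between log2 fold change and merged exon length was −0.322 over 9177 genes (91.4% of those tested). The median log2 fold change ran from 0.48 in genes of up to 500 bp to −0.25 in genes above 8000 bp. The correlation of a library's deviation from the gene mean over all libraries with length was 0.27 to 0.293 in the control libraries and −0.299 to −0.24 in the knockout libraries. These deviations cancel over the libraries of a gene, so the opposite signs of the genotypes restate the trend and do not replicate it. After a smooth length trend was removed from each library, an alternative chosen after seeing the data, 3537 of 9177 genes were changed, 1762 higher and 1775 lower. The median of antimicrobial peptides (16 of 17 members kept) was then 3.71, that of Bomanins (17 of 17) 2.31 and that of phototransduction genes (27 of 30) −0.64.

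**Figure D4:**
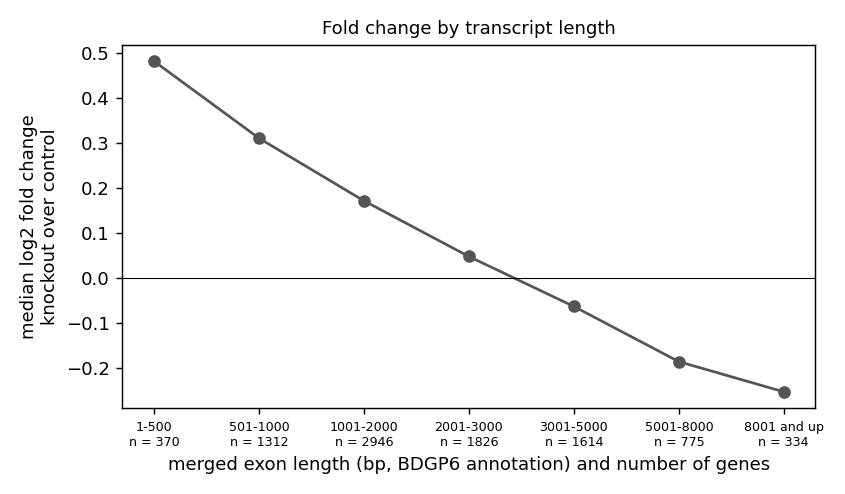
Median log2 fold change (knockout over control, y axis) of genes grouped by merged exon length in bp of the BDGP6 annotation (x axis, with the number of genes per class). The line falls from 0.48 for 370 genes of up to 500 bp to −0.25 for 334 genes above 8000 bp.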

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

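The removal of the length trend and the test without small RNA genes were chosen after seeing the data. The fall of Nlg3 kept its direction and its call under 18 alternatives, from −1.13 to −0.64. The antimicrobial peptide list did so under 21, where its mean log2 fold change exceeded that of other genes by 3.65 to 4.62. Leaving out each library in turn gave 3508 to 3782 changed genes, 2121 to 2213 higher and 1387 to 1576 lower. The 4337 changed genes came to 2794 at an adjusted p below 0.01 and 1079 with an absolute log2 fold change of at least 1, as the stricter thresholds require. Lower genes rose from 1806 to 2732 under quantile normalization and to 3924 with columns rescaled to 1000000, where higher genes fell from 2531 to 1444, since both scalings lower the larger knockout columns. The number of lists past the test was 21, with 20 at a minimum mean FPKM of 5, after rescaling to 1000000 and after removal of the length trend, 10 under an estimated correlation and 27 under fry.

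For lists, the direction is that of the camera test, and the values here are the mean log2 fold change minus that of other genes, which can differ in sign from the test. Reversals after removal of the length trend were neuroligin (0.054) and unc-13 (0.089) among genes, and neuroligins and neurexins (0.0015), presynaptic release machinery (−0.0092) and neurotransmitter synthesis (0.066) among lists. Quantile normalization reversed Yp1 (−0.072), Yp2 (−0.10) and the female-biased list (−0.35), and rescaling to 1000000 reversed Nrx-IV (−0.14) and AGO2 (−0.015). A minimum mean FPKM of 5 reversed the male-biased list (0.51), as it drops low testis and accessory gland genes. Without the member with the smallest p, the Imd list (−0.062) and the female-biased list (−0.37) reversed. For these reversals the cause was not tested beyond the construction of each alternative. Of 567 values for the other 27 lists, 536 kept direction and side of the threshold, 15 lost the call, 9 gained one and 7 reversed. Of 2702 values for 151 named genes the numbers were 2656, 34, 6 and 6. Most of these genes were named for a large change or a small p in the same libraries. Their stability therefore says little about the other changed genes.

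Replicate numbers do not pair the libraries, since deviations of same-numbered libraries correlated at −0.0069, −0.144 and 0.0541, and not every library correlated best with its own number. The fit with the replicate block gave 3859 changed genes, 2321 higher and 1538 lower, with Nlg3 at −0.82 and 21 lists past the test. Knockout library 1 had the lowest relative depth, 0.547, and a change near an FPKM of 1 was least detectable there.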

Other observations

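Tests chosen only after the result was seen are those of the gene families, of fat body tissue, of another stock difference, of the removal of the length trend and of the gap between lists under quantile normalization alone. Beyond the fixed lists, 37 families of genes with a shared symbol and at least 8 tested members were tested with camera, and 2 passed. Osiris genes, insect-specific membrane proteins clustered on chromosome 3R, were lower in the knockout for 9 of 9 members, with a median log2 fold change of −1.91 (adjusted p = 3.66e-05, and adjusted p = 0.317 with an estimated correlation). Osi2 fell from 19.1 to 0.793 FPKM, Osi6 from 46.9 to 6.82 and Osi7 from 34.6 to 5.33 (means, n = 3 per genotype). The alpha-esterase genes, also on chromosome 3R, were higher for 8 of 9 members, with a median of 1.02 (adjusted p = 0.00538, and adjusted p = 0.364 with an estimated correlation). Both families thus lie on the chromosome arm of Nlg3, and a link of their change to that locus was not tested. alpha-Est7 rose from 32.2 to 105 FPKM and alpha-Est9 from 24.9 to 54.1. Both families passed again after removal of the length trend (adjusted p = 3.24e-05 and 0.00181).

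The rise of 16 of 17 antimicrobial peptide genes was weighed first. Scaling of the columns is argued against, since the lowest median of the list over the 3 other scalings was 4.58. The median of the peptides exceeded that of the fat body list by 3.66 (permutation of list membership, p = 0.00017). The permutation treats genes as independent, although some are near-identical copies and all come from the same libraries. The fat body list also holds lipid metabolism genes, which would rise less with more fat body where other tissues express them. A larger share of fat body tissue therefore stays open. Another difference between the stocks or their collection cannot be told apart from loss of Nlg3, because the control and the knockout come from different stocks. Expression of w differed by 4.46 ± 0.112 (SE), and whether that signal comes with the Nlg3 alleles is not known. A regulation of immune genes by Nlg3, an infection or different gut bacteria in a stock, fly age, the mix of sexes and handling all stay open. Shares of tissues other than fat body were not tested, although the medians of the gut and male-biased lists were 1.59 and 1.5.

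The rise of tim, per, vri and cwo is consistent with heads collected at different times of day. Clk and cry, which cycle in antiphase, had a mean log2 fold change of −0.691 ± 0.056 (SE). That mean rested mainly on Clk, at −1.22, and cry alone did not pass. The SE leaves out the difference between these genes. Scaling is argued against, since the lowest mean of the 4 genes over the other scalings was 1.6. The labels give no collection time, and an effect of the knockout on the clock stays open and untested.

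For the higher ribosomal protein genes and lower phototransduction genes, the length trend is argued against as the whole cause. After its removal the ribosomal median moved from 0.68 to 0.33 (quartiles 0.175 and 0.429) and that of phototransduction from −0.48 to −0.638 (quartiles −0.775 and −0.243). The values after removal cover the 70 of 81 and 27 of 30 members with a known length. One factor per column moves both lists alike and so cannot open the gap of 1.16 between their medians, and under quantile normalization, which can change it, the gap was 1.04, with the ribosomal quartiles at 0.0991 and 0.4 and those of phototransduction at −1.04 and −0.433. A smaller share of eye tissue stays open, since the SD of the phototransduction fold changes, 0.478 against a median standard error of 0.0554, exceeded 2 standard errors as in each of the 28 lists and decides nothing. The 5 compound eye rhodopsins ninaE, Rh3, Rh4, Rh5 and Rh6, chosen after their values were seen, changed by −0.54 to −0.46 and the ocellar Rh2 by 0.41. Other members of the list lay outside that range, with inaF-B, norpA and rdgA at −1.83, −1.36 and −1.33 and Arr1 at 0.185. RNA quality or library preparation differing between the genotypes and an effect of the knockout stay open as well.

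Among 10 splits of the 6 libraries into 3 and 3, 1, the real one, gave as many as 4337 changed genes, and the highest of the others gave 3. The splits are too few for a share under 0.05.

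A hypothesis was that variants carried along with the Nlg3 alleles on 3R could change neighbouring genes. Within 2 Mb of Nlg3, 46 of 354 genes (13%) were changed by at least 1 on the log2 scale, against 11.2% elsewhere (permutation by 9176 circular shifts, one-sided p = 0.253). The test leaves open a smaller effect near the locus and effects of variants on other chromosomes.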
